A study of Rattus norvegicus with 14 samples.

How the data were processed

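Single-cell RNA libraries were made from cultured left-ventricle cardiac fibroblasts of adult male SHR rats with droplet-based, UMI-counting chemistry that reads transcript ends, and sequenced as 254 bp paired-end reads, per the labels' protocols. About 4000 cells were loaded per sample. Samples were assigned to groups from their titles, which name 7 control and 7 ACEI samples. Both groups carry the replicate numbers 1 to 7, and nothing in the labels says that equal numbers share an animal, a day or a batch. The values are whole-number UMI counts per gene and cell barcode, deposited without normalisation; they were made with Cell Ranger 3.0.2 on the rat genome build Rnor_6.0 (rn6), per the submitters' processing notes. Those notes also name Seurat without saying for which step, and no filter on cells beyond the choice of barcodes is given in the sources used here. Gene symbols and identifiers were used as the files pair them, for 25399 genes, of which 261 symbols were shared by 2 or more genes. A table of gene names from another rat assembly (GRCr8) was used for names of pseudogene copies only, and no coordinates were taken from it.

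Cells were kept with at least 500 genes, at least 1000 UMIs and at most 20% of UMIs from mitochondrially encoded genes, which 33864 of 41944 barcodes passed. Doublets were treated with Scrublet as run in scanpy 1.11.5: in each library the cells with the highest scores were removed at a rate of 0.8% per 1000 barcodes, 858 cells in all. No correction was made for free RNA. The retained cells were clustered with the Leiden method at resolution 1 on 30 principal components of 2000 variable genes with 15 neighbours. A cluster was given a name ending in -like where at least 3 markers fixed for 1 cell type reached 20 CPM and 4 times the median of the other clusters. Fibroblast-like clusters, being the majority, needed instead 3 fibroblast markers above 100 CPM, the collagens Col1a1, Col1a2 and Col3a1 at 25% or more of the level of the median cluster, and at most 1 raised marker of any other type. Clusters with 3 raised markers of more than 1 type stayed unnamed, as did those with endothelial or blood cell markers and collagens above 50% of the median cluster. The marker sets were fixed in advance, and these levels after the data were first seen. The marker sets covered fibroblasts, endothelial cells, smooth muscle cells or pericytes, macrophages or monocytes, cardiomyocytes, epicardial or mesothelial cells, Schwann or neural cells, T or NK cells, B cells, neutrophils or mast cells, adipocytes and erythrocytes. Fibroblast-like cells were clustered again at resolution 0.5, after centring each library, for shares and tests within clusters. As no gene was called between groups, none was left out of this clustering.

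For gene tests, UMI counts were summed per library over the fibroblast-like cells, giving 1715634 to 17168500 counts per library. The main test was edgeR 4.0.16 with TMM scaling, its expression filter by group, a robust quasi-likelihood fit of group alone and Benjamini-Hochberg adjustment at 0.05. Log2 differences are ACEI minus control with 95% intervals, and list means per library used log2 CPM with a prior count of 2. Clusters with at least 20 cells in at least 5 libraries per group, and the endothelial-like class in the 10 libraries with at least 20 of its cells, were tested in the same way. The difference in the ACEI effect between clusters 1 and 2 was tested in limma 3.58.1 with voom and the library as a random block. The 42 pairs of libraries within a group differed by a chi-square per degree of freedom of 3.76 to 57.7 over genes, so no library was counted as a copy of another.

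A total of 24 gene lists was tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry. They were fibrillar collagens and their crosslinking, non-fibrillar collagens, matrix glycoproteins and proteoglycans, myofibroblast contractile genes, TGF-beta targets, matrix proteases and inhibitors, resting fibroblast genes, growth factors and receptors, and the renin-angiotensin and kinin system. Further lists were cytokines, chemokines and NF-kB targets, interferon response, complement, S phase, G2 and M phase, p53 targets and senescence, NRF2 antioxidant genes, and immediate early genes. The last were YAP targets, unfolded protein response, cholesterol synthesis, glycolysis and hypoxia, nuclear genes of oxidative phosphorylation, and 2 lists made by name pattern, cytosolic ribosomal proteins and mitochondrially encoded genes. Lists were allowed to share members.

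Named genes followed a rule. It took up to 10 called genes per direction, or the 3 of smallest p in each direction where none passed, a fixed panel of 12 fibrosis genes, and the 2 members of smallest p in each list without a called member. Genes known only by locus identifiers were not named, and a few other genes are not reported here. The group of each sample, the cell filter, the gene lists, the marker sets, the naming rule, the tests and most alternatives were set before the data were examined.

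Shares of cell classes and clusters were compared with exact two-sided permutation tests over all 3432 splits of 14 libraries into 7 and 7, whose smallest p is 0.000583, with Benjamini-Hochberg adjustment within each family. Distances between cells, the SD of the fibrogenic share and the share of cycling cells were computed after thinning every cell at random to 1000 UMIs, because 2000 UMIs would have kept 14.9% of the cells in the shallowest library. A cell counted as cycling with 3 or more UMIs from the G2 and M list.

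The tests were tried on simulated counts with the real means, library sizes and spread and 200 genes changed by known folds. On 9928 genes edgeR recovered 13.6%, 49.3% and 89.4% of genes changed 1.25-, 1.5- and 2-fold, with 4 false among 105 calls. DESeq2 1.42.0 recovered 18.2%, 55.2% and 89.4% with 11 false among 119, and limma recovered 12.1%, 44.8% and 86.4% with 5 false among 100. Genes and libraries were drawn independently, unlike the real counts, so recovery in the real libraries may differ. A list shifted by 1.25-fold was called by camera, with the estimated correlation and by fry, and camera called 0 other lists. That simulation drew genes independently with 1 common spread, whereas the members of the shifted list, the fibrillar collagens, correlated at 0.132 in the real libraries. It therefore cannot give the false calls or the power of the list tests in these data. The median half-width of the 95% interval of a log2 difference in the real libraries was 0.26.

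Alternatives were DESeq2 size factors, DESeq2's Wald test, limma's voom with sample weights, no gene filter, a minimum mean of 5 CPM, the replicate number as a block, 1 surrogate variable from sva 3.50.0, and the median UMI count or mitochondrial share as covariate. Others were no cell filter, a stricter one (1000 genes, 2000 UMIs, 10% mitochondrial), all retained cells, cells without cycling cells, 1091 cells per library, equal counts per library, and leaving out each library. Clusters were also made at resolutions 0.3 and 1, without centring and without cell cycle genes. A looser cell filter (300 genes, 500 UMIs), tests without the 3 shallowest libraries, the 2 library sets as a block and within each set, clustering of thinned cells, and thinning to 2000 UMIs were chosen after seeing the data. Computation used R 4.3.3, python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, igraph 0.11.9 and matplotlib 3.10.9.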

Results

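Cardiac fibroblasts were taken from the left ventricles of adult male spontaneously hypertensive rats (SHR), an inbred strain with inherited high blood pressure, and were kept in culture for 3 days. Single-cell RNA was then sequenced in 7 control libraries and 7 libraries from rats that had received an angiotensin-converting enzyme inhibitor (ACEI) in their drinking water for 2 weeks, followed by 2 weeks without the drug. The design asks whether fibroblasts carry a lasting difference after a short, discontinued blockade of the renin-angiotensin system, in their fibrogenic genes and in the variety of their subpopulations. The sources used here do not state that each library came from a separate animal, so p-values measure the spread between these libraries. The 14 libraries held 41944 cell barcodes and 133024803 UMIs (unique molecular identifiers, each standing for 1 captured transcript). Per library, the barcodes ranged from 1358 to 5213, against about 4000 cells loaded. In order of replicate number, the control libraries held 19011606, 15936596, 8154529, 7939235, 5041855, 10006280 and 3019224 UMIs, and the ACEI libraries 10060780, 5891437, 11599256, 8725713, 14708123, 8897654 and 4032515. After filtering, 33006 cells were retained, of which 31327 were fibroblast-like. The share of barcodes retained was 38.6% in control replicate 7, 43.5% in ACEI replicate 2 and 61.0% in ACEI replicate 7, and lay between 85.7% and 93.0% in the other libraries. Median UMIs per retained cell ran from 1420.5 in control replicate 7 to 6500 in control replicate 1. The libraries fell into 2 sets along the first principal component of their summed fibroblast-like counts, which held 26.0% of the variance and did not follow the groups. Set 1 held control replicates 1, 2, 3 and 7 with ACEI replicates 1, 2 and 3, and set 2 the other 7 libraries.

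No gene of a fixed fibrosis panel passed the test between groups in the fibroblast-like cells, and the log2 differences lay between -0.36 and 0.09. Col1a1, which encodes a chain of type I collagen, averaged 2736 ± 188 CPM (counts scaled by library total; SD, n = 7) in control and 2689 ± 239 CPM (SD, n = 7) in ACEI libraries, a log2 difference of -0.02 (SE 0.07). Postn, which encodes the matricellular protein periostin, averaged 357 ± 55.5 against 329 ± 54.4 CPM (log2 difference -0.12, SE 0.11), with 6 of 7 ACEI libraries below the control median. The values for Acta2, the smooth muscle actin of myofibroblasts, were 708 ± 173 and 641 ± 102 CPM (-0.14, SE 0.14). The panel gene of the largest difference was Cthrc1, a secreted protein of activated fibroblasts, at 29.3 ± 9.20 CPM in control and 23.7 ± 7.49 CPM in ACEI libraries. Its log2 difference was -0.36 (SE 0.23, 95% interval -0.85 to 0.13) and 6 of 7 ACEI libraries lay below the control median. The log2 differences were -0.12 (SE 0.11; 6 of 7 ACEI libraries below the control median) for Col3a1, 0.03 (SE 0.08) for fibronectin (Fn1), -0.08 (SE 0.10) for connective tissue growth factor (Ctgf), and 0.09 (SE 0.09) for the collagen crosslinking enzyme Lox. They were -0.01 (SE 0.14) for the metalloproteinase inhibitor Timp1 and -0.00 (SE 0.08) for Tgfb1. For both Ctgf and Lox 6 of 7 ACEI libraries lay above the control median, which for Ctgf is opposite to the sign of its difference. Each panel gene had an adjusted p of 0.9999 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Directions were not kept everywhere: within library set 1 Postn had 0.07 and Col3a1 0.06, Fn1 had -0.11 within set 2 and -0.03 without ACEI replicate 1, and Timp1 had 0.14 within set 2 and 0.08 without ACEI replicate 1. Tgfb1 kept its sign in 19 of 34 settings (-0.07 to 0.05) and Col1a1 in 33 of 34. The drug's target Ace gave 3 UMIs in all control and 0 in all ACEI libraries, and the angiotensin receptor gene Agtr1a gave 26 and 20 UMIs. Both were too low to test at this depth.

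**Figure D1:**
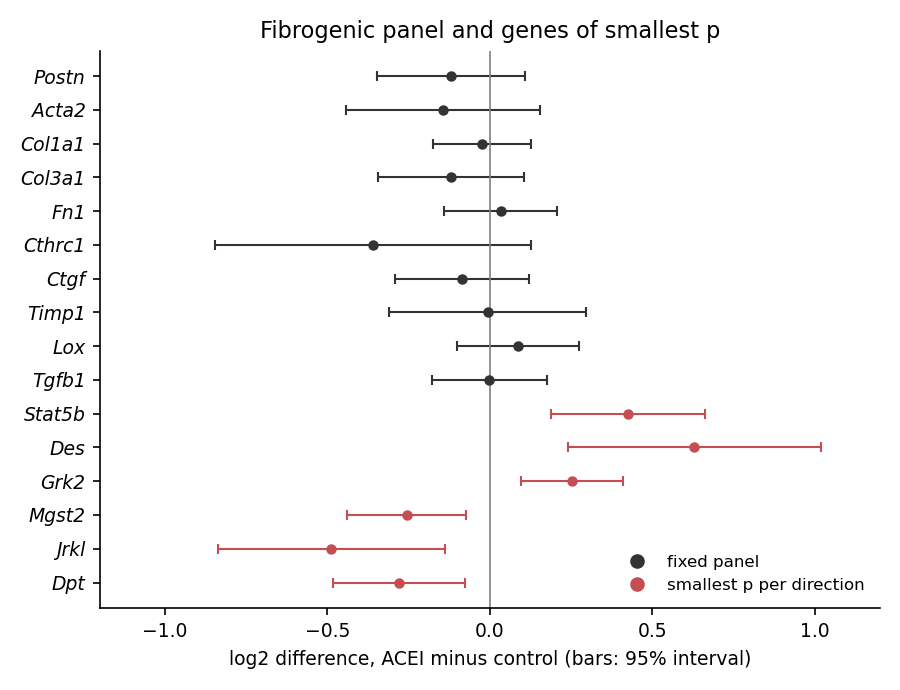
Log2 difference in expression (ACEI minus control, x axis) in fibroblast-like cells for the 10 tested genes of the fixed fibrogenic panel (dark points) and the 3 genes of smallest p in each direction (red points); bars are 95% intervals from edgeR over 7 control and 7 ACEI libraries. All 10 panel intervals include 0, and the red genes, picked for their small p, did not pass after adjustment.

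Across the transcriptome, 0 genes rose and 0 fell among 9935 tested at an adjusted p of 0.05. An unadjusted p below 0.05 was reached by 109 genes, where 497 are expected with no effect and no structure among the libraries. DESeq2 called 0 genes with 81 below 0.05, limma called 0 with 241, and edgeR with the replicate number as a block called 0 with 327. Without control replicate 3 the edgeR count below 0.05 was 205, without ACEI replicate 1 it was 174 and without ACEI replicate 5 it was 176, with 0 called each time. The genes of smallest p that were higher in ACEI libraries were Stat5b, a transcription factor of cytokine and growth hormone signalling, Des and Grk2. Stat5b averaged 6.34 ± 0.609 CPM (SD, n = 7) in control and 8.61 ± 0.983 CPM in ACEI libraries, a log2 difference of 0.43 (SE 0.11), and 7 of 7 ACEI libraries lay above the control median. Des, which encodes the intermediate filament desmin, averaged 2.42 ± 0.403 and 3.95 ± 0.938 CPM (0.63, SE 0.19). Grk2, a kinase that desensitises G protein-coupled receptors, averaged 23.6 ± 1.99 and 28.0 ± 1.34 CPM (0.25, SE 0.08). Those lower in ACEI libraries were the glutathione transferase Mgst2 (47.6 ± 6.42 against 39.8 ± 3.52 CPM, -0.26, SE 0.09), Jrkl (5.26 ± 0.941 against 3.57 ± 0.770 CPM, -0.49, SE 0.17) and the matrix protein gene Dpt (49.7 ± 4.91 against 40.9 ± 6.46 CPM, -0.28, SE 0.10). None of these 6 genes passed, each with an adjusted p of 0.9999. The biological coefficient of variation between libraries was 16.8%. Among 1535 genes above 100 CPM, the 95% interval lay within 1.5-fold of no difference for 1435. In simulated libraries of the same depth and spread per gene, the test recovered 49.3% of genes changed 1.5-fold and 89.4% of genes changed 2-fold. The simulation drew genes and libraries independently, without the variation that the real libraries shared along their first principal component. The recovery of the real test may therefore differ.

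Gene lists for matrix production and remodelling showed no shift that passed the main competitive set test (limma's camera with a preset correlation, adjusted over 24 lists). Of 22 fibrillar collagen and crosslinking genes, 16 had higher and 6 lower values in ACEI libraries (median log2 difference 0.03, adjusted p = 0.627; median -0.02 without ACEI replicate 4), while the mean of the list lay below the control median in 5 of 7 ACEI libraries. The members of smallest p were P4ha2, a collagen prolyl hydroxylase (0.16, SE 0.10; -0.03 within library set 1), and Col3a1. Of 14 non-fibrillar collagens, 10 were lower (-0.05, adjusted p = 0.391), with Col4a4 at -0.33 (SE 0.21) and Col7a1 at 0.25 (SE 0.19; -0.19 without cycling cells). The median of that list was 0.02 without control replicate 3. Among 38 matrix glycoproteins and proteoglycans, 17 were higher and 21 lower (adjusted p = 0.817); here the median was -0.02 and the mean -0.01 while the test pointed upward. Prelp (0.20, SE 0.09) and tenascin C (Tnc; 0.16, SE 0.09) led by p. Of 24 myofibroblast contractile genes, 17 were higher (median 0.03, adjusted p = 0.186), with the myosin light chain kinase Mylk at 0.39 (SE 0.19) and Zyx at 0.09 (SE 0.07). Of 29 TGF-beta target genes, 13 were higher and 16 lower (-0.01, adjusted p = 0.817), with Klf10 at 0.26 (SE 0.12) and Tgif1 at -0.24 (SE 0.14). Of 27 proteases and inhibitors of the matrix, 20 were lower (-0.06, adjusted p = 0.131), with Adamts10 at 0.25 (SE 0.11) and Serpine2 at -0.35 (SE 0.18). Of 25 genes typical of resting fibroblasts, 17 were lower (-0.04, adjusted p = 0.137), with Dpt at -0.28 and the transcription factor Tcf21 at -0.33 (SE 0.20). The contractile list passed without control replicates 6 (adjusted p = 0.0267) or 7 (0.0273), without ACEI replicate 1 (0.0402) and in limma's voom with sample weights (0.0182), in 4 of 36 settings. The protease list passed in 6, among them without control replicates 4 (0.0428) or 7 (0.0331) and without ACEI replicate 3 (0.0416), and the resting fibroblast list in 8, among them without control replicate 4 (0.0033) and without ACEI replicates 2 (0.0207) or 3 (0.0416). None of the 3 lists passed with an estimated correlation in all libraries, with adjusted p = 0.855 for the contractile, 0.488 for the protease and 0.809 for the resting fibroblast list. No member of any of the 24 lists passed over all genes tested, and the number adjusted over the list alone was also 0 in each.

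The set test did call 3 lists, all lower in ACEI libraries. With a correlation between members estimated from these libraries, no list passed: the adjusted p = 0.809 with an estimated correlation for G2 and M, 0.472 for p53 and 0.488 for NRF2. Among 61 tested genes of the G2 and M phases, 46 were lower and 15 higher (median log2 difference -0.04, adjusted p = 0.0463), and 4 of 7 ACEI libraries lay below the control median of the list. Cdk1, the kinase that drives entry into mitosis, averaged 235 ± 29.2 CPM (SD, n = 7) in control and 205 ± 17.8 CPM in ACEI libraries (log2 difference -0.19, SE 0.08), and Gas2l3 differed by -0.22 (SE 0.12). Of 22 p53 target and senescence genes, 16 were lower (median -0.09, adjusted p = 0.0463), led by the cell cycle inhibitors Cdkn2b (-0.26, SE 0.14) and Cdkn2a (-0.22, SE 0.12), and 5 of 7 ACEI libraries lay below the control median. Of 29 antioxidant genes controlled by NRF2, 18 were lower (median -0.04, adjusted p = 0.0476), with the glutathione transferase Gsta4 at -0.34 (SE 0.12) and Nfe2l2, which encodes NRF2 itself, at -0.17 (SE 0.07). In 7 of 7 ACEI libraries the mean of that list lay below the control median. The rotation test fry gave an adjusted p of 0.947 for each of the 3 lists.

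All 3 calls depended on single libraries and on settings. The G2 and M list no longer passed without control replicate 1 (adjusted p = 0.126), control replicate 3 (0.292), control replicate 7 (0.0766), ACEI replicate 1 (0.895, with a median of 0.00) or ACEI replicate 4 (0.122). The p53 list no longer passed without control replicate 1 (0.0822), control replicate 3 (0.189), control replicate 5 (0.0542), ACEI replicate 1 (0.160) or ACEI replicate 5 (0.0551). The NRF2 list was lost without control replicates 1 (0.0833), 2 (0.329), 3 (0.292) or 5 (0.0688) and without ACEI replicates 4 (0.122), 5 (0.0858), 6 (0.168) or 7 (0.175). With the stricter cell filter the adjusted p was 0.0615 for G2 and M, 0.0961 for p53 and 0.0553 for NRF2, and limma's voom with sample weights gave 0.30 for G2 and M (median -0.01) and 0.114 for p53. With the library set as a block the 3 lists had adjusted p of 0.111, 0.0696 and 0.245, with medians of -0.03 for G2 and M, -0.10 for p53 and -0.05 for NRF2, close to those without it. Within set 1 the G2 and M list had a median of -0.10 (adjusted p = 0.000346), and within set 2 a median of 0.02 in the other direction (adjusted p = 0.351). In set 1 the mean log2 CPM of the list was 5.27 in ACEI replicate 1, against 5.63 and 5.62 in ACEI replicates 2 and 3. The control libraries of that set had 5.58 to 5.70, so its difference rested largely on ACEI replicate 1.

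The remaining lists described other programmes, and none passed the main test. For growth factors and receptors, 30 of 49 genes were lower (median -0.03, adjusted p = 0.157), although Tgfb3, a transforming growth factor, had 90.7 ± 7.47 CPM (SD, n = 7) in control and 110 ± 22.3 CPM in ACEI libraries (log2 difference 0.27, SE 0.11) against -0.44 (SE 0.19) for the BMP antagonist Grem1. Of 23 cytokine, chemokine and NF-kB target genes, 13 were lower (adjusted p = 0.817), with opposite values for the chemokines Cxcl10 (0.70, SE 0.26) and Cxcl1 (-0.27, SE 0.11). The 23 interferon response genes split 11 to 12 (adjusted p = 0.817; Isg15 0.45, SE 0.19; Psmb9 -0.22, SE 0.11), and the 8 complement genes 4 to 4 (0.817; Colec12 0.16, SE 0.09; Cd59 0.20, SE 0.16). The 8 tested genes of the renin-angiotensin and kinin system also split 4 to 4 (adjusted p = 0.817), with Atp6ap2 at -0.12 (SE 0.08) and Agtrap at 0.12 (SE 0.10). In the cytokine, interferon, complement, renin-angiotensin and glycolysis lists the median lay between -0.02 and -0.00 while the test pointed upward. For glycolysis and hypoxia 19 of 34 genes were lower (0.391; Pdk1 0.20, SE 0.10; Egln1 0.38, SE 0.21). Of 45 S phase genes, 23 were higher (adjusted p = 0.816; Wdr76 0.58, SE 0.30).

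Of 35 genes of the unfolded protein response, 18 were lower (adjusted p = 0.817; Trib3 0.32, SE 0.21; Ern1 -0.18, SE 0.12), as were 20 of 28 genes of cholesterol synthesis and uptake (0.137, 0.0234 without control replicate 4 and 0.809 with an estimated correlation; Nsdhl -0.15, SE 0.11; Idi1 -0.12, SE 0.10). Of 34 immediate early genes, which also respond to cell dissociation, 21 were higher (0.137, 0.0315 without control replicate 5 0.0333 without ACEI replicate 2 and 0.472 with an estimated correlation; Ier5 0.18, SE 0.10; Fosb 0.44, SE 0.25). Of 22 YAP targets, 14 were higher (0.817; Fam49a 0.26, SE 0.12; Cyr61 -0.19, SE 0.10). The 49 nuclear genes of oxidative phosphorylation were divided 26 to 23 (0.817; Ndufv2 -0.12, SE 0.08; Uqcrc2 -0.12, SE 0.09), and 10 of 13 mitochondrially encoded genes were lower (0.391; Mt-nd4l -0.44, SE 0.43; Mt-nd1 -0.08, SE 0.10). Of 86 genes taken as cytosolic ribosomal proteins, 57 were higher (adjusted p = 0.0908 and 0.881 with an estimated correlation). They were picked by symbols that start with Rpl or Rps and a digit, without a check of what each gene encodes. Rpl39l had 1.13 (SE 0.58) and Rps19 had 0.31 (SE 0.27). This list passed in 12 of 36 settings, among them within library set 2 (0.0296) and with the stricter cell filter (0.0217). It also passed without control replicates 2 (0.0489), 4 (0.0234), 6 (0.0267) or 7 (5.9e-05) and without ACEI replicates 3 (0.0416) or 5 (0.000443). Ribosomal protein genes share sequence with many near-identical copies, so their counts may be uncertain, which was not tested for this list.

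The cultures consisted almost wholly of fibroblast-like cells in both groups. Their share was 94.0% ± 4.43 (SD, n = 7) in control and 95.8% ± 3.11 (SD, n = 7) in ACEI libraries (exact permutation p = 0.406, adjusted p = 0.559). Endothelial-like cells made up 2.58% ± 2.24 and 2.21% ± 1.85 (exact p = 0.717), and macrophage- or monocyte-like cells 0.708% ± 0.955 and 0.301% ± 0.463 (exact p = 0.356). Epicardial- or mesothelial-like cells made up 0.531% ± 0.969 and 0.185% ± 0.299 (exact p = 0.448). Clusters that could not be named held 2.15% ± 1.31 and 1.52% ± 0.666 of the cells (exact p = 0.294). They were 263 cells with both mural and endothelial transcripts and 326 cells with fibroblast collagens and macrophage transcripts. No cluster was named from the fixed markers of smooth muscle cells or pericytes, cardiomyocytes, adipocytes, Schwann or neural cells, T, NK or B cells, neutrophils or mast cells, or erythrocytes. No adjusted p lay below 0.559 over the 5 exact two-sided tests, and the smallest p the 3432 splits allow is 0.000583. The endothelial-like cells had a median of 1506 UMIs against 3094 in fibroblast-like cells, near the minimum of 1000 UMIs. The 3 libraries with the fewest UMIs per cell had the smallest endothelial-like shares of their groups, at 0.264% in control replicate 7 and 0.220% and 0.277% in ACEI replicates 2 and 7.

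The fibroblast-like cells divided into 6 clusters whose shares differed by less than the spread between libraries. Cluster 1, marked by Olfml3, Neu1 and Ctsl, held 29.5% ± 6.13 (SD, n = 7) of fibroblast-like cells in control and 29.6% ± 6.89 in ACEI libraries (exact permutation p = 0.973). Its top genes also included Nasp and Mcm3 of the S phase list and Hmmr and Dlgap5 of the G2 and M list. Cluster 2, marked by the mitotic genes Top2a, Ube2c, Plk1 and Aurka, held 25% ± 2.65 and 23.7% ± 2.22 (exact p = 0.334). Cluster 3, marked by the chemokines Ccl7 and Ccl2 with Tnc and Mfap5, held 20.8% ± 1.92 and 20.6% ± 1.80 (exact p = 0.836). Cluster 4, marked by Cyp1a1, Nov, Car3 and Fibin, held 14.1% ± 7.90 and 15.4% ± 8.22 (exact p = 0.758), and ranged over single libraries from 5.45% in ACEI replicate 2, at a median of 1521 UMIs per cell, to 31.4% in ACEI replicate 5, at 5070.5 UMIs. Cluster 5, marked by mitochondrial transcripts and Fth1, held 10.5% ± 2.46 and 10.6% ± 1.67 (exact p = 0.927). Cluster 6, with 37 cells in all, held 0.134% ± 0.18 and 0.101% ± 0.120 (exact p = 0.696). Every adjusted p over the 6 clusters was 0.973. Clusters differed in depth, with a median UMI count of 0.80 times that of the cell's own library in cluster 1 and 1.63 times in cluster 5. Cycling cells made up 81.2%, 91.9%, 17.9%, 71.8% and 63.7% of clusters 1 to 5, so they were not confined to cluster 2. In 5 other clusterings of the same cells 0 clusters passed, with the smallest adjusted p between 0.850 and 0.998.

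**Figure D2:**
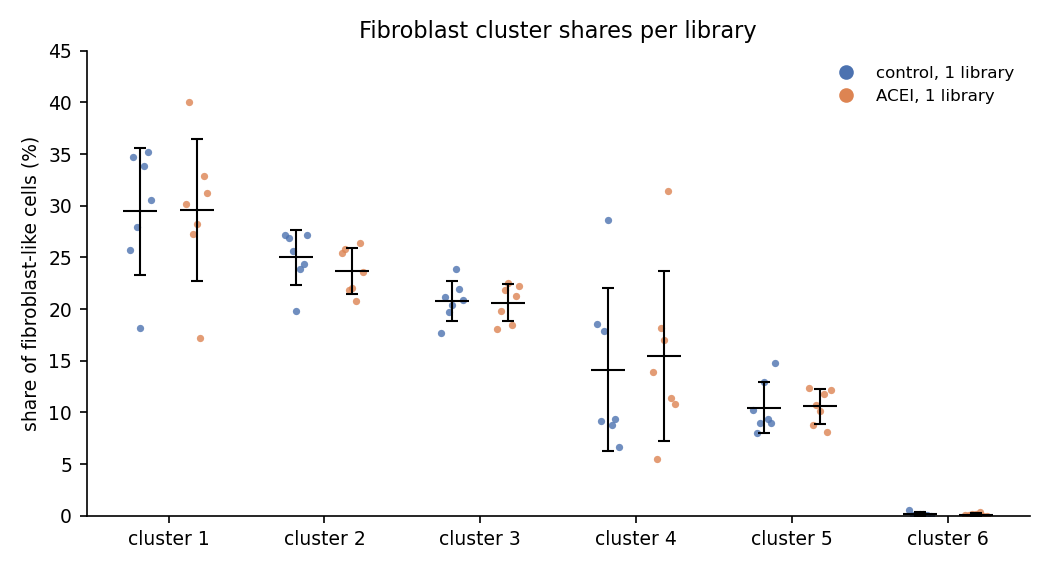
Share of fibroblast-like cells (%, y axis) in each of 6 clusters (x axis) for 7 control and 7 ACEI libraries; each point is 1 library, and the horizontal bars with whiskers are the mean and SD of a group. The 2 groups overlap in each cluster, and cluster 4 spans from 5.45% to 31.4% of a library's cells.

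The variety of the fibroblast-like cells within a library differed between groups by less than the spread between libraries. The Shannon entropy of the cluster shares, in nats, was 1.53 ± 0.0470 (SD, n = 7) in control and 1.53 ± 0.0596 in ACEI libraries (exact permutation p = 0.857). The mean distance between cells (1 minus Pearson's r over variable genes, after thinning each cell to 1000 UMIs) was 0.480 ± 0.00811 and 0.479 ± 0.00820 (exact p = 0.832). The share of a cell's UMIs in collagen, matrix glycoprotein and contractile genes averaged 2.87% ± 0.162 and 2.87% ± 0.153, and its SD between cells was 0.976 ± 0.102 and 0.950 ± 0.0995 percentage points (exact p = 0.633). The adjusted p was 0.857 for all 3 measures. Without thinning the distance was 0.348 ± 0.0514 and 0.368 ± 0.0445 (exact p = 0.452) and the SD of the share 0.882 ± 0.103 and 0.863 ± 0.0969 (exact p = 0.717). No cell was lost to thinning, since 1000 UMIs was also the minimum for a retained cell.

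Most fibroblast-like cells carried transcripts of dividing cells. The share of cycling cells, those with at least 3 UMIs from G2 and M genes after thinning to 1000 UMIs, was 68.3% ± 1.16 (SD, n = 7) in control and 66.6% ± 2.80 (SD, n = 7) in ACEI libraries. The difference of -1.72 percentage points was larger than the SD of the control libraries but smaller than that of the ACEI libraries. It did not pass (exact permutation p = 0.163), and 2 of 7 ACEI libraries lay above the control median. Unthinned shares were 89.7% ± 6.49 and 87.0% ± 5.80 (exact p = 0.437). Single libraries moved it: it was -2.38 without ACEI replicate 5, with an exact p = 0.0332, and -0.955 without ACEI replicate 1, with an exact p = 0.325. Within library set 1 it was -3.17 (exact p = 0.200) and within set 2 it was -0.644 (exact p = 0.657), where the smallest p that 7 libraries allow is 0.0571. By the same measure 24.3% of endothelial-like and 10.7% of macrophage- or monocyte-like cells counted as cycling cells, at median depths of 1506 and 1364 UMIs against 3094 for fibroblast-like cells. Free RNA in the droplets can add G2 and M UMIs to any cell and was not subtracted.

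**Figure D3:**
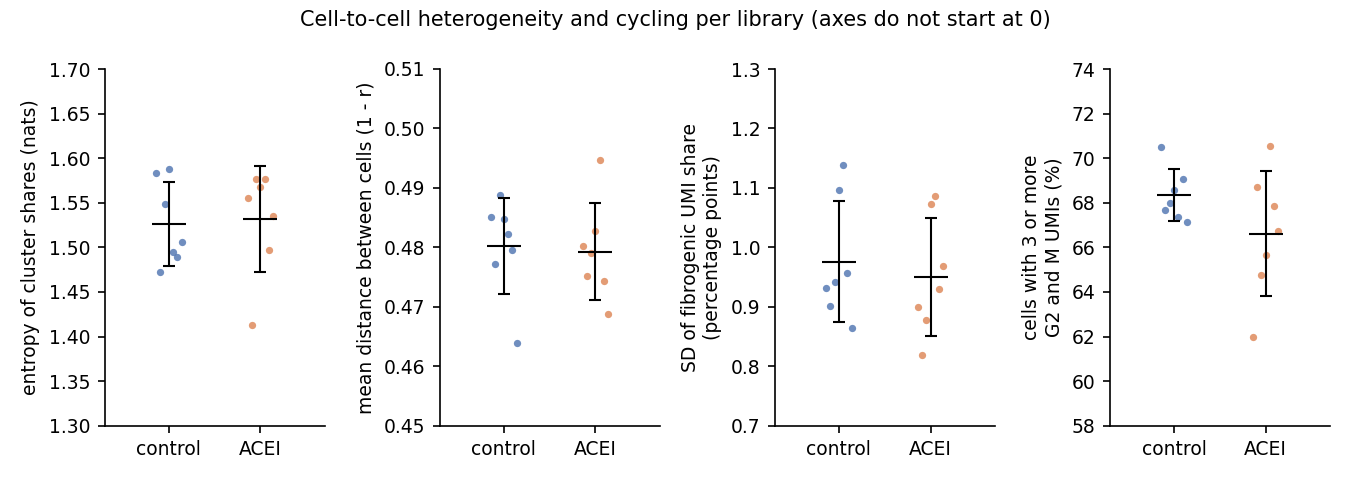
Entropy of cluster shares (nats), mean distance between cells (1 minus Pearson's r), SD of the fibrogenic UMI share (percentage points) and share of cells with 3 or more G2 and M UMIs (%), each for 7 control and 7 ACEI libraries; points are libraries, bars with whiskers are group means and SDs, and the y axes do not start at 0. The groups overlap in all 4 measures, with group means of 68.3% and 66.6% for the last.

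Within single fibroblast clusters, no panel gene passed the test. Cthrc1 had the largest panel difference in each of clusters 1 to 5, with log2 differences of -0.31 (SE 0.21), -0.55 (SE 0.20), -0.43 (SE 0.19), -0.42 (SE 0.32) and -0.46 (SE 0.23). Its unadjusted 95% interval left out 0 in cluster 2 (-0.96 to -0.14) and cluster 3 (-0.83 to -0.03), as did that of Postn in cluster 2 (-0.39 to -0.01). Postn ranged from -0.20 (SE 0.09) in cluster 2 to -0.04 (SE 0.12) in cluster 5, and Col1a1 from -0.09 (SE 0.09) in cluster 4 to 0.05 (SE 0.10) in cluster 5. In edgeR's quasi-likelihood test 0 genes rose or fell in clusters 1 to 5, with 141, 152, 139, 87 and 157 genes at an unadjusted p below 0.05 among 7422, 8047, 7310, 6882 and 6587 tested. DESeq2 also called 0, with 93, 100, 83, 46 and 104 below 0.05. In simulated clusters, with libraries again drawn independently, the test recovered 63.6%, 56.7%, 46.9%, 34.4% and 52.3% of genes changed 1.5-fold. In cluster 3 the carbonic anhydrase gene Car3 had the smallest p in edgeR, with a log2 difference of -0.86 (SE 0.19, adjusted p = 0.687). It passed without control replicate 1 (-0.98, adjusted p = 0.0436) and without the filter on low genes (-0.85, adjusted p = 0.0330). Car3 also passed with the replicate number as a block (-0.87, adjusted p = 0.0238), which called 2 loci without a gene name as well. Car3 also marks cluster 4, where it averaged 196 CPM and whose share differed widely between libraries. The difference in ACEI effect between clusters 1 and 2, the largest, was tested as an interaction in limma. It called 0 of 8261 genes, with 432 below 0.05 and a smallest adjusted p of 0.416. The edgeR test with the library as a fixed block called 0 with 443 below 0.05 and a smallest adjusted p of 0.0694. Pbx3 (-0.80, SE 0.18) and Sars2 (-0.80, SE 0.18) had the smallest p, and the simulated interaction test recovered 17.9% of genes changed 1.5-fold. The simulation drew the 2 clusters independently, without the within-library correlation of 0.44 in the real counts, so the recovery of the real test may differ. Car3, Pbx3 and Sars2 were chosen for naming after their values were seen.

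Endothelial-like cells, the largest other class, were numerous enough to test in 10 libraries. Klf4, a transcription factor that responds to blood flow, had a log2 difference of 0.70 (SE 0.23) and the chemokine gene Ccl7 of -1.51 (SE 0.50), each with an adjusted p of 0.9997 in edgeR; both were chosen after their values were seen. In edgeR's quasi-likelihood test 0 of 2182 genes rose or fell, with 33 at an unadjusted p below 0.05, and DESeq2 called 0 with 15 below 0.05. Without the filter on low genes Ccl7 passed in edgeR (-1.49, adjusted p = 0.000578). Ccl7 marks a cluster of the fibroblast-like cells, where it averaged 4228 CPM. The simulated test recovered 8.20% of genes changed 1.5-fold and 56.9% of genes changed 2-fold in this class, so most 1.5-fold differences would have been missed with these cells and libraries.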

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

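No test in this part was chosen after its result was seen. A library is listed where its gap to the nearest of the other 6 libraries of its group exceeded 0.568 of the group's range. This was met by 7 of 70 groups of values, where independent normal values give 3.5 by chance. Small shares bounded at 0 may depart from that assumption, and the genes of smallest p entered the screen through their p. The share of barcodes retained was 38.6% in control replicate 7, against 88.1% to 93.0% in the other control libraries. Epicardial- or mesothelial-like cells made up 2.64% of control replicate 4 and at most 0.772% of the other control libraries. Macrophage- or monocyte-like cells made up 2.71% of control replicate 1 and at most 1.06% of the others. Cluster 6 of the fibroblast-like cells held 0.513% of control replicate 1, with at most 0.183% in the other control libraries, and 0.343% of ACEI replicate 5, with at most 0.132% in the other ACEI libraries. Fn1, which encodes fibronectin, reached 797 CPM in ACEI replicate 1, against 550 to 650 CPM in the other ACEI libraries. Stat5b, the gene of smallest p, lay at 5.03 CPM in control replicate 4, below the 6.25 to 6.80 CPM of the other control libraries.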

How the results depend on the processing

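The tests by library set, with a looser cell filter, without the 3 shallowest libraries and on thinned clusters were chosen after seeing the data. Of 508 alternative values for 25 results, 485 were counted as the same result, which does not show that each kept its direction. The mean distance between cells, which passed in neither case, was lower in ACEI libraries after thinning (0.479 against 0.480 in control). Without thinning it was higher in ACEI libraries (0.368 against 0.348). Over 34 settings 0 genes were called in fibroblast-like cells (edgeR, DESeq2 or limma), with 71 to 348 at an unadjusted p below 0.05, and 51 of 62 named genes kept their sign.

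The number of gene lists called, 3 by camera, was 0 with the 2 library sets as block, without a cell filter, without cycling cells, with equal counts per library, with an estimated correlation and with fry. It was 1 within library set 2 and with equal cells per library, 6 in all retained cells and 7 without the 3 shallowest libraries. Leaving out 1 library gave 0 (control replicate 1 or 3) to 7 (control replicate 4), with 5 without control replicate 6 or 7 or ACEI replicate 2, 6 without ACEI replicate 3 and 1 without ACEI replicate 4. Lists gained in some settings were cytosolic ribosomal proteins (12 of 36 settings), resting fibroblast genes (8), matrix proteases (6), contractile genes (4), immediate early genes (3), cholesterol synthesis (2), glycolysis (1) and growth factors (1). For G2 and M, p53 and NRF2 in this order, the adjusted p was 0.0588 each without a cell filter, 0.697, 0.190 and 0.271 without cycling cells (medians -0.05, -0.07 and -0.05), and 0.0854, 0.361 and 0.0854 with equal counts (-0.05, -0.04 and -0.06). G2 and M and p53 had 0.247 with equal cells, p53 had 0.0782 at a mean of 5 CPM and 0.0567 with the looser cell filter, and NRF2 had 0.106 and 0.0810 with the median UMI count or mitochondrial share as covariate and 0.0645 without the 3 shallowest libraries. The G2 and M list turned to a median of 0.0249 within library set 2. Without the gene filter 1 gene was called in endothelial-like cells (Ccl7) and 1 in cluster 3 (Car3). Cluster 3 had 0 to 1 called genes when libraries were left out, the 1 being Car3 without control replicate 1. The difference in cycling cells ranged from -2.38 without ACEI replicate 5 (exact p = 0.0332) to -0.955 without ACEI replicate 1. The cause was not tested for any of these.

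With the replicate block 0 genes were called in fibroblast-like cells, with 327 at an unadjusted p below 0.05 in edgeR, against 109 without it. In cluster 3 the block called 3 genes, Car3 (-0.87, adjusted p = 0.0238 in edgeR) and 2 loci without a gene name, LOC103690996 (0.55) and LOC100362027 (0.35). It called 4 lists, with cytosolic ribosomal proteins higher (adjusted p = 0.000279), and changed no other count of calls by over 1.5 times. Deviations of libraries with equal numbers correlated at 0.0169 to 0.527, over 0.1 in 5 of 7 pairs, and 7 of 14 libraries correlated best with their own number. The mean correlation was 0.281 for equal numbers and -0.0478 for other numbers across groups. As not all pairs passed 0.1, the numbers were not taken as pairs, although these values point to some structure shared along them. The main test leaves such structure in its error, so its p-values may be too large. With the block the smallest adjusted p in fibroblast-like cells was still 0.9996 in edgeR. Clustering with called genes kept in was identical, as 0 genes were called, and the macrophage class had no value without a cell filter or with the stricter one. The 3 shallowest libraries limit what low genes and rare cell types can show.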

Other observations

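The tests on the 3 gene lists, the splits of the libraries and the test of ACEI treatment on the library sets were chosen only after the result was seen. Single clusters of fibroblast-like cells held larger but uncertain differences in genes chosen here after their values were seen. In cluster 5, the BMP antagonist gene Grem1 had a log2 difference of -0.91 (SE 0.22), the growth factor gene Areg of -0.91 (SE 0.24) and Mgst2 of -0.60 (SE 0.15), each with an adjusted p of 0.999 in edgeR. In cluster 3, marked by Ccl7 and Ccl2, Nfe2l2 had -0.29 (SE 0.09), with an adjusted p of 0.9998 in edgeR.

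Of the 6 clusters, cluster 4 had the largest SD of its share in percentage points; relative to its mean, cluster 6 with 37 cells varied more. It was marked by Cyp1a1, a target of the aryl hydrocarbon receptor, at 235 CPM against a mean of 9.84 CPM in the other clusters, and by Nov at 691 against 75.7 CPM and Car3 at 196 against 24.8 CPM. Its share of fibroblast-like cells was 31.4% in ACEI replicate 5 and 28.6% in control replicate 4, and 5.45% in ACEI replicate 2 and 6.68% in control replicate 7. Median UMIs per retained cell were 5070.5 and 5630 in the first pair and 1521 and 1420.5 in the second. Depth did not order all libraries, as the deepest, control replicate 1 at 6500 UMIs, had 18.6%, and control replicates 2 and 3 had 9.15% and 17.8% at 3932 and 3393 UMIs. When cells were thinned to equal depth before clustering, 5 clusters formed, and the markers of cluster 4 had no cluster of their own. Cyp1a1, Nov and Car3 were then top genes of the same cluster as the mitotic genes Plk1, Top2a, Ube2c and Aurka.

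The library sets along the first principal component followed the numbers in the sample descriptions, whose meaning is not given in the sources used here. The 6 libraries numbered 5 to 12 lay in set 1, the 7 numbered 13 to 19 in set 2, and control replicate 7, numbered 20, in set 1. Among genes picked after their values were seen, Eef1a1 ran from 107 to 179 CPM in set 1 and from 331 to 1273 CPM in set 2, and Btf3 from 20.2 to 50.2 and from 81.3 to 403 CPM. A test argued against ACEI treatment, as 8 of 14 libraries lay on their group's side. After thinning to equal totals 13 of 14 libraries kept their side, which argues against noise from unequal totals. Other effects of depth stay open, because thinning summed counts keeps the expected share of each gene. Any effect of UMIs per cell or of the cell filter would remain in those shares. Reads shared between genes and pseudogene copies may contribute but stay open, because only 70% of the 200 genes of largest loadings had a name in the table used, under the 80% needed. Among the 200 named genes of largest loadings 19.5% had a named pseudogene copy, against a mean of 10.6% and at most 17.5% in 1000 matched sets. As the test is void below 80%, no conclusion is drawn from these values. No biological explanation other than treatment was tested.

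The lower G2 and M, p53 and NRF2 lists in ACEI libraries may reflect chance. Of 100 splits of the libraries, the real one included, 37 called as many lists, with 3 in the real split and 11 in the highest other. That count took in any of the lists, so it bears on their number and not on each of these 3. Many other splits called the G2 and M list, but few called the p53 or the NRF2 list. These 3 were picked because the real split called them, so chance cannot be excluded. Correlation between the members of a list is consistent with the calls, as the lowest adjusted p of the 3 was 0.472 with an estimated correlation. Fewer cycling cells in ACEI libraries stay open. Without cycling cells the G2 and M median was -0.0454 against -0.0371 with them, but those cells were picked by genes of the same list. A lasting effect of ACEI treatment on these genes also stays open.

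Splits of the libraries say nothing about chance for the counts of called genes, because the real counts were 0 and 100 of 100 splits gave as many by construction. The highest other split called 307 genes in all fibroblast-like cells, 5, 9, 2, 12 and 19 in clusters 1 to 5, 26 in endothelial-like cells and 1 for the difference between clusters 1 and 2. The split with 307 genes kept both libraries of 6 replicate numbers together. Splits that kept 0, 2, 4 and 6 numbers together numbered 3, 39, 52 and 6. Their median number of genes at an unadjusted p below 0.05 was 119, 252, 506.5 and 813.5, which points to a structure of the samples. The real split, with 109 such genes in edgeR, kept 0 numbers together and was 1 of those 3. For the difference between clusters 1 and 2, 432 genes had an unadjusted p below 0.05 in limma, against 435 in the highest other split, and 5 of 100 splits had as many, the real one included.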
